A study of Homo sapiens with 16 samples.

How the data were processed

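MCF7 is an established estrogen-responsive human breast cancer cell line. The series measured RNA in MCF7 cells (WT) and in an MCF7 line labelled as knockout (KO) for TDP2, which encodes an enzyme that removes trapped topoisomerase 2 from DNA ends. Each line was left untreated or given 10 nM 17β-estradiol (E2) for 2 h. Bulk RNA-seq gave 8 libraries, 2 for each of the 4 groups, which the labels call biological replicates. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries. Single-cell RNA-seq gave 1 sample for each of the same 4 conditions. All 16 deposited samples were mapped to a group from their labels, and the entries that held only sample tags or shared captures carried no further condition.

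The deposited bulk table held expected (estimated) counts per Ensembl gene that the authors had not scaled between libraries, and 42.9% of its values were not whole numbers. The submitters' processing notes name MultiQC 1.14, STAR 2.7.5c, RSEM 1.3.1, Cell Ranger without a version, and the builds GRCh38 and hg38, with no role or order, so the step that made each file is not stated. The deposited table held 20544 genes, none with a value of 0 in any library, so a gene without counts in some library is not in it. Whether counting used strand is not stated, so values of overlapping genes are uncertain. A second bulk table deposited by the authors held estimated counts scaled by TMM and corrected for a batch, per its name. It had 254 values below 0 and does not state its batch variable, so it served only to check named genes and the pairing of replicates. The deposited single-cell table held UMI counts per gene and cell barcode, with 33694 genes and 12 sample tag entries, which stayed out of all totals. A deposited table of labels gave each barcode the condition that the authors had assigned. Of 2162 barcodes, 19 had no condition and were left out, which left 2143 cells. How cells were called and filtered is not stated, and no doublet caller was run.

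Ensembl identifiers were matched to GENCODE 29 (GRCh38), which placed 20467 of the bulk genes and gave 17884 of them a symbol. Of the bulk genes, 14587 were protein coding. Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr, which kept 19458. They were scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 model of all 8 libraries. The model had the 4 groups and the replicate number as a block, which left 3 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, and a false discovery rate of 0.05 was the threshold. The comparisons were the E2 effect in WT, the E2 effect in the KO-labelled libraries, the difference of these effects, and KO-labelled against WT without and with E2. Log2 fold changes are given with standard errors (SE), and CPM (counts scaled to a common library size) with the SD of 2 libraries.

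The block was fixed in advance, because the authors deposited a table named as batch corrected. The replicate number is the only labelled factor that crosses the 4 groups, and the labels themselves state only the numbers. The correlation of the replicate differences between groups lay between 0.13 and 0.66 in all group pairs. It was lowest for WT E2, at 0.13 with KO-labelled E2 and 0.17 with KO-labelled untreated libraries. In the authors' batch-corrected table the same correlations lay between −0.46 and 0.3.

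The genes to name were fixed before the data were examined. For E2 they were MYC, CCND1, GREB1, TFF1, PGR and EGR3, and the 10 largest rises and 8 largest falls past the threshold with a mean log2 CPM of at least 1. For KO-labelled against WT they were TDP2, its neighbours and the 12 largest changes each way by the same filter. For the difference of the E2 effect they were MYC, CCND1 and the 8 smallest p-values each way past the threshold, or otherwise the 5 smallest each way, named as not passing. Genes had to change the same way in both replicate pairs and to have a gene name, so unnamed clone-based loci were excluded. Each list was represented by the 2 to 4 members with the smallest p-values. For single cells the rule took the bulk genes and the 10 largest folds each way whose interval excluded a fold of 1.5, with at least 100 UMIs over both samples, of which the text names a part. The single-cell examples within lists and the members set beside a list for their opposite sign were chosen after their values were seen.

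Also fixed at that point were 24 gene lists: estrogen-induced, estrogen-repressed, immediate early, MYC targets and ribosome biogenesis, cell cycle S, cell cycle G2M, double-strand break repair, p53 targets, apoptosis, interferon-stimulated, NF-κB inflammatory, unfolded protein and ATF4, hypoxia and glycolysis, cholesterol synthesis, aryl hydrocarbon receptor (AHR) targets, histones, mitochondrially encoded, housekeeping, luminal epithelial, mesenchymal and basal, fibroblast, leukocyte, other epithelial (HEK and HeLa) markers, and TDP2 neighbours. Of their entries, 1 matched no identifier. Lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01 and adjusted over the 24 lists of a comparison. The correlation estimated for the E2 effect in WT was 0.801 for G2M, 0.701 for S phase and 0.307 for estrogen-induced genes. It was 0.005 for AHR targets. Where the estimate exceeds the preset, the preset p-values are too small, and no list passed camera with the estimate. Camera with an estimated correlation, camera without the block and fry were the alternatives fixed in advance. Leaving out each library was added for lists after seeing the data.

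Other bulk alternatives fixed in advance were no block, DESeq2 size factors (RLE in edgeR), upper quartile scaling, other count filters (none, or 1 CPM), the DESeq2 1.42.0 Wald test, limma-voom, a model of only the 4 libraries compared, and leaving out each library. Voom with sample quality weights, a robust edgeR fit, contrasts averaged over the other factor and values without WT E2 replicate 2 were chosen after seeing the data.

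With 1 single-cell sample per condition no test between conditions was made. UMIs were summed per sample and given as CPM with exact Poisson 95% intervals, and folds with exact conditional binomial 95% intervals. These cover counting error only. Shares of cells with a UMI have exact binomial intervals and were also taken after thinning every cell to 7500 UMIs. List medians used CPM plus 1 and were placed among 10000 random lists of the same size, matched on mean expression in 40 bins. The alternatives were cells with at least 500 genes and at most 25% mitochondrial UMIs, totals without mitochondrial and ribosomal protein genes, and thinning. Bulk and single-cell folds were correlated across genes with at least 50 UMIs, or 200 as an alternative, among 17772 shared identifiers. Single-cell steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

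The bulk scripts were tested on simulated data first. With 200 changed genes among 19225, the edgeR model recovered 28% of genes changed 2-fold and 88% of those changed 4-fold for the E2 effect in WT, and 10 of its 126 calls were false. For the difference of the E2 effects it recovered 7% and 63% of these among 19258 genes, and 3 of 73 calls were false. False calls were 15 of 117 for the E2 effect in KO-labelled libraries among 19248 genes, and 15 of 124 without and 10 of 126 with E2 for KO-labelled against WT among 19255 genes, so the share of false calls exceeded the nominal threshold in 4 of the 5 comparisons. On simulated counts the single-cell intervals covered the true fold in 95.3% to 95.5% of genes in the 4 comparisons. Between 10765 and 11213 of the 12495 genes run entered this check, which was made in the same step as the real values. Of 50 lists of 40 genes drawn at random and scored on the real E2 folds in WT, 4 lay outside the central 95% of their matched random lists.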

Results

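RNA was measured in MCF7 breast cancer cells (WT) and in an MCF7 line labelled as knockout for TDP2 (KO-labelled), without treatment and after 2 h with 10 nM E2, the main ligand of the estrogen receptor. The comparisons ask which genes answered E2 at this early time and whether the answer differed in the KO-labelled line. Bulk libraries (n = 2 per group) held between 51186045 and 105719464 estimated counts, a ratio of 2.07. The 10 most abundant genes took between 4.95% and 6.21% of a library, and mitochondrial genes between 1.53% and 3.38%. The single-cell samples held 598 untreated WT cells, 369 WT cells with E2, 429 untreated KO-labelled cells and 747 KO-labelled cells with E2. Their cells carried sample tags, their median depth lay between 29130 and 33660 UMIs per cell, and their summed depth between 13150030 and 26262426 UMIs.

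TDP2 (ENSG00000111802, chromosome 6, 24649977 to 24667033, minus strand, GRCh38) did not differ past the threshold between KO-labelled and WT libraries. Its level was 59.8 ± 9.02 CPM (SD, n = 2) in untreated WT, with 66.2 and 53.5 in the 2 libraries, and 52.9 ± 12.8 CPM (61.9 and 43.8) in untreated KO-labelled libraries. After E2 it was 45.9 ± 17.3 CPM (58.1 and 33.7) in WT and 66.9 ± 5.97 CPM (62.7 and 71.1) in KO-labelled libraries. The log2 difference of KO-labelled from WT was −0.19 (SE 0.24, adjusted p = 0.898) untreated and 0.60 (SE 0.24, adjusted p = 0.735) after E2 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The neighbours ACOT13 (24667035 to 24705065), C6orf62 (24704861 to 24720836) and GMNN (24774931 to 24786099) had log2 differences of 0.17, −0.02 and −0.33 untreated and of 0.54, 0.46 and −0.03 after E2. With 1 library left out the TDP2 difference ranged from −0.29 to −0.10 untreated and, without KO-labelled E2 replicate 2 and 1, from 0.23 to 0.95 after E2. ACOT13 ranged from 0.07 to 0.30 and from 0.14 to 1.00. C6orf62 (−0.22 to 0.16) turned untreated, GMNN ranged from −0.53 to −0.10 untreated, and GMNN (−0.21 to 0.15) turned after E2. In single cells TDP2 stood at 23.2 CPM (95% interval 21.2 to 25.4) in untreated WT and 22.5 CPM (20.4 to 24.8) in untreated KO-labelled cells. After E2 it stood at 23.3 CPM (20.7 to 26.0) and 22.2 CPM (20.4 to 24.1). The log2 differences of KO-labelled from WT cells were −0.05 (−0.24 to 0.15) and −0.07 (−0.27 to 0.14), and 0.207 and 0.198 after thinning every cell to 7500 UMIs, which leaves fewer TDP2 UMIs. The edited position is not in the labels and an edit can leave the transcript level unchanged, so these levels did not check the knockout label.

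In WT, E2 raised ENSG00000261578, an unnamed gene at chromosome 11, 76800364 to 76804555, from 5.81 ± 0.463 to 43.7 ± 0.262 CPM. Its log2 fold of 2.90 (SE 0.27, adjusted p = 0.0236, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) was the only one past the threshold. It has no gene name, so it lies outside the naming rule, was chosen after its values were seen, and lies just beyond TSKU (76782251 to 76798154, same strand), which encodes a secreted proteoglycan, so its reads and those of TSKU may not be separable. TSKU itself went from 71.6 ± 18.5 to 355.2 ± 5.44 CPM, with a log2 fold of 2.31 (SE 0.26) and an adjusted p of 0.0596. The classical E2 targets all had higher values in both replicate pairs without passing. MYC, the growth regulator at chromosome 8, 127735434 to 127741434, went from 119.6 ± 45.7 to 235.4 ± 62.8 CPM, a log2 fold of 1.04 (SE 0.29, adjusted p = 0.542), with 1.68 in the first and 0.33 in the second pair. Its log2 fold was 1.55 without WT E2 replicate 2 and 0.45 without WT E2 replicate 1. CCND1, which encodes cyclin D1, went from 380.7 ± 30.3 to 592.7 ± 14.0 CPM, a log2 fold of 0.64 (SE 0.21). EGR3, an immediate early transcription factor, went from 5.79 ± 3.88 to 27.2 ± 8.90 CPM, a log2 fold of 2.41 (SE 0.35). GREB1 had a log2 fold of 1.51, TFF1 of 0.71 and PGR, the progesterone receptor, of 1.45. Without WT E2 replicate 1 the log2 folds were 2.08 for GREB1, 0.94 for TFF1, 2.09 for PGR and 2.81 for EGR3. A fit without a WT E2 library leaves 1 in that group, so its calls do not measure the spread of WT E2. Without WT E2 replicate 1 only WT E2 replicate 2 is left, which stood apart from the other libraries (below). Leaving out WT E2 replicate 2 gave log2 folds of 0.71 for GREB1, 0.44 for TFF1 and 0.37 for PGR. Across the 19458 genes tested 1148 had an unadjusted p under 0.05, where chance gives 973, and the median SE was 0.302. DESeq2 called 153 genes and voom 2. Without the replicate block no gene was called and ENSG00000261578 had an adjusted p of 0.117. The call was also lost without either untreated WT library or either KO-labelled E2 library, while leaving out WT E2 replicate 1 gave 1599 calls and leaving out WT E2 replicate 2 gave 8.

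As groups, estrogen-induced genes rose and G2M genes fell in WT. Of 55 estrogen-induced genes 52 had positive folds, with a median log2 of 1.04 (camera, adjusted p = 1.43e-45, and 0.488 with an estimated correlation). None passed over all genes, and 31 rose when adjusted over the list alone, among them TSKU, KCNK5 (2.67), EGR3 and ADORA1 (2.60). All 55 G2M genes, which act in mitosis, had negative folds, with a median of −0.82 (camera, adjusted p = 2.45e-33, and 0.488 with an estimated correlation), including CDK1 (−1.05), SMC4 (−0.83), NUF2 (−1.13) and HMMR (−1.41). These medians were 0.46 and −0.24 without WT E2 replicate 2, and without WT E2 replicate 1 the G2M median was −1.63. The folds nearest 0 with 1 library left out were −0.63 for CDK1 and −0.46 for SMC4 (without WT untreated replicate 2) and −0.56 for NUF2 (without WT E2 replicate 2). MYC target and ribosome biogenesis genes rose, 47 of 52 with positive folds and a median of 0.36 (camera, adjusted p = 1.89e-10, and 0.496 with an estimated correlation), such as PPRC1 (1.02), PPAN (0.66) and BYSL (0.58). The median was 0.13 without WT E2 replicate 2, with PPRC1 at 0.53 and PPAN at 0.42. Interferon-stimulated genes fell, with 6 of 45 positive and a median of −0.25 (camera, adjusted p = 1.63e-07, and 0.488 with an estimated correlation), such as IFIT1 (−1.23), IFIT3 (−1.11) and OASL (−0.72).

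Other groups called in WT each lost the call when 1 library was left out. Estrogen-repressed genes fell by a median of 0.46 (camera, adjusted p = 8.35e-06, and 0.488 with an estimated correlation), with CCNG2 at −1.40 and TP53INP1 at −1.24, though GATA4, a member of that list, stood at 4.33. Their median was −0.16 without WT E2 replicate 2 (adjusted p = 0.0972), with CCNG2 at −0.83 and TP53INP1 at −0.62, and −0.91 without WT E2 replicate 1. Cholesterol synthesis genes rose by a median of 0.29 (camera, adjusted p = 0.00016, and 0.56 with an estimated correlation), with DHCR7 at 0.79 and LDLR at 0.72, and without WT E2 replicate 2 their median was −0.03 (adjusted p = 0.247), with DHCR7 at 0.17 and LDLR at 0.03. It was 0.60 without WT E2 replicate 1. AHR targets, which include the xenobiotic enzymes CYP1A1 (3.24) and CYP1B1 (3.95), rose by 0.31 (camera, adjusted p = 0.0191, and 0.488 with an estimated correlation), and by 0.01 without WT E2 replicate 2 (adjusted p = 0.45), where CYP1A1 stood at −0.11 and CYP1B1 at −0.51. Their median was 0.49 without WT E2 replicate 1. Double-strand break repair genes (median −0.08), NF-κB genes (0.15) and TDP2 neighbours (−0.35) each had an adjusted p of 0.0442 by camera, and of 0.562, 0.56 and 0.557 with an estimated correlation. Without the replicate block NF-κB genes (0.361) and TDP2 neighbours (0.0632) lost the call, and all 3 lost it without WT untreated replicate 2, with medians of 0.01 for repair, 0.015 for NF-κB and −0.12 for TDP2 neighbour genes. TDP2 neighbours lie on chromosome 6, where WT E2 replicate 2 lay lower by a median of −0.171 (below), and without that library their median was −0.16 and the call was lost (adjusted p = 0.0906). The repair median was −0.22 without it, and the NF-κB median 0.64 without WT untreated replicate 1. The remaining lists did not pass camera, with adjusted p of 0.741 for apoptosis, 0.339 for S phase, 0.128 for fibroblast, 0.757 for other epithelial, 0.503 for leukocyte, 0.159 for luminal and 0.405 for mesenchymal and basal genes. It was 0.112 for histones, p53 targets and ATF4 genes, 0.382 for housekeeping, 0.319 for hypoxia, 0.153 for immediate early and 0.387 for mitochondrially encoded genes. Fry called only hypoxia (adjusted p = 0.0448). With 1 library left out S phase genes passed in either direction: their median was −0.37 without WT E2 replicate 2 (camera, adjusted p = 6.53e-12, and 0.628 with an estimated correlation) and 0.23 without WT untreated replicate 2 (camera, adjusted p = 0.00663, and 0.868 with an estimated correlation). Mitochondrially encoded genes passed without WT E2 replicate 2, at 0.30 (camera, adjusted p = 0.00104, and 0.628 with an estimated correlation), and immediate early genes without WT untreated replicate 1, at 0.42 (camera, adjusted p = 0.000296, and 0.416 with an estimated correlation). Leaving out WT E2 replicate 1 let histones (−0.57), luminal genes (−0.13) and ATF4 genes (−0.365) pass (camera, adjusted p = 0.00169, 0.0086 and 0.00215, and at least 0.539 with an estimated correlation).

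**Figure D1:**
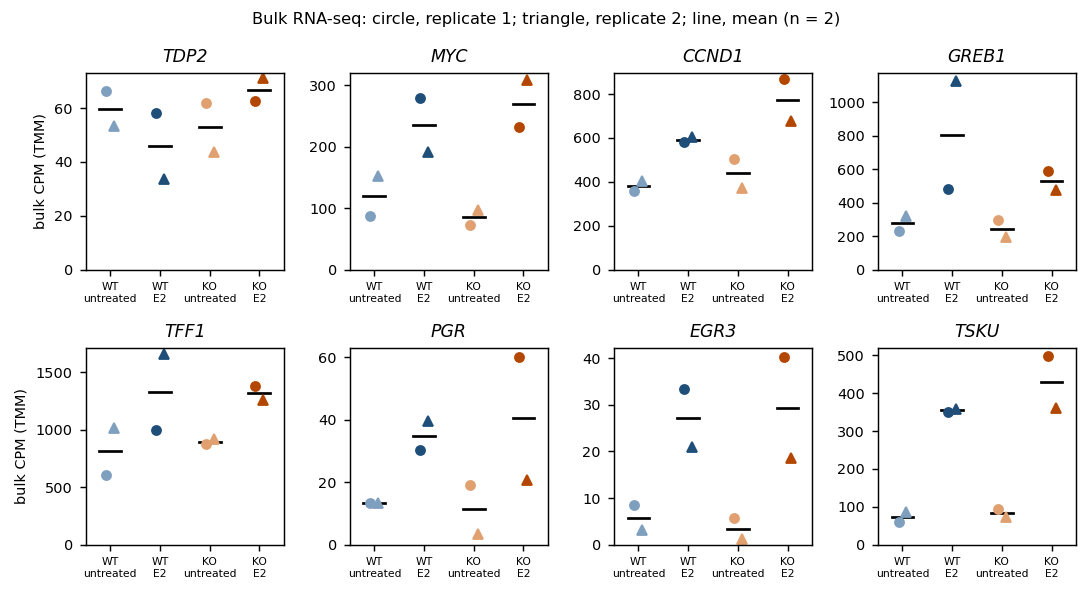
Bulk CPM (y axis, from 0) of 8 genes in the 4 groups, with a circle for replicate 1, a triangle for replicate 2 and a line for their mean. TDP2 stands between 33.7 and 71.1 CPM in every group, and MYC at means of 119.6, 235.4, 85.2 and 270.1 CPM.

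In KO-labelled libraries E2 raised 3 genes and lowered none in the model of all 8 libraries (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). All groups share their spread in that model, so the spread of the WT E2 pair enters the SE of KO-labelled folds. Without WT E2 replicate 2 the MYC log2 fold in KO-labelled libraries was 1.67 with an SE of 0.18. A model of the 4 KO-labelled libraries alone called far more genes (below). ENSG00000261578, again named after its values were seen, rose from 7.10 ± 2.40 to 49.3 ± 11.5 CPM, a log2 fold of 2.80 (SE 0.27, adjusted p = 0.0317). TSKU rose from 83.5 ± 14.1 to 429 ± 96.1 CPM, a log2 fold of 2.36 (SE 0.26, adjusted p = 0.036). EGR3 rose from 3.43 ± 3.12 to 29.4 ± 15.3 CPM, a log2 fold of 3.30 (SE 0.36, adjusted p = 0.036). MYC went from 85.2 ± 17.3 to 270.1 ± 53.4 CPM, a log2 fold of 1.67 (SE 0.29, adjusted p = 0.269), with 1.67 and 1.66 in the pairs, and CCND1 from 440.2 ± 93.5 to 774.2 ± 134.8 CPM, a log2 fold of 0.82 (SE 0.21). GREB1 had a log2 fold of 1.12, TFF1 of 0.57 and PGR of 1.94, and none of these passed with all libraries. MYC, GREB1 and PGR passed without WT E2 replicate 2 (adjusted p = 0.000765, 0.0373 and 0.0385) and also without WT E2 replicate 1. Leaving out KO-labelled untreated replicate 2 gave 0.66 for GREB1 and 1.18 for PGR, leaving out KO-labelled untreated replicate 1 gave 1.75 and 3.33, and leaving out KO-labelled E2 replicate 1 gave 0.21 for TFF1. At an unadjusted p under 0.05 there were 494 genes, voom called 4 and DESeq2 79. Without the replicate block no gene was called, with adjusted p of 0.0993 for ENSG00000261578 and TSKU and 1 for EGR3, and leaving out any KO-labelled library also left 0 calls. Leaving out WT E2 replicate 1 gave 101 calls and leaving out WT E2 replicate 2 gave 96.

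Estrogen-induced genes rose in KO-labelled libraries as well: 52 of 55 had positive folds, with a median log2 of 0.87 (camera, adjusted p = 4.63e-76, and 0.243 with an estimated correlation). Of these, 2 passed over all genes and 31 rose when adjusted over the list alone, such as TSKU, EGR3, SIAH2 (1.78) and KCNK5 (2.46). Immediate early genes, which respond within the first hours of a stimulus, rose with 30 of 43 positive and a median of 0.32 (camera, adjusted p = 5.31e-08, and 0.769 with an estimated correlation), such as EGR3, SGK1 (2.31), MYC and FOS (2.08). That call was lost without KO-labelled untreated replicate 1 (adjusted p = 0.0703), and the median was 0.06 without KO-labelled E2 replicate 2 and 0.50 without KO-labelled E2 replicate 1. MYC target and ribosome biogenesis genes rose by a median of 0.19 in 42 of 52 (camera, adjusted p = 5.41e-07), such as RRS1 (0.69) and NIP7 (0.64). Mitochondrially encoded genes fell by a median of 0.30, and interferon-stimulated genes rose by a median of 0.15 with 31 of 45 positive (camera, adjusted p = 0.000573 and 0.0183). Estrogen-repressed genes fell by a median of 0.27 (camera, adjusted p = 0.0488), with GATA4 at 3.56. With an estimated correlation these 4 lists had an adjusted p of 0.994. Each of these 4 calls was lost without KO-labelled E2 replicate 1, where the mitochondrial median was 0.03 and that of MYC target and ribosome biogenesis genes 0.04. Without KO-labelled untreated replicate 2 the interferon median was 0.002 and the estrogen-repressed median −0.09. The largest medians were −0.67 and −0.55 for mitochondrial and estrogen-repressed genes without KO-labelled E2 replicate 2, and 0.38 and 0.35 for ribosome biogenesis and interferon genes without KO-labelled untreated replicate 1, where GATA4 stood at 5.80. Without the replicate block the interferon (adjusted p = 0.124) and estrogen-repressed lists (0.263) were not called. The other lists had adjusted p between 0.107 and 0.989. Among them S phase genes passed in either direction with 1 library left out, at −0.32 without KO-labelled untreated replicate 2 (camera, adjusted p = 1.92e-14, and 0.863 with an estimated correlation) and at 0.30 without KO-labelled untreated replicate 1 (camera, adjusted p = 0.0333, and 0.877 with an estimated correlation). G2M genes (−0.19) and histones (−0.30) passed without KO-labelled E2 replicate 2 (camera, adjusted p = 0.00382 and 0.00358, and 0.988 and 0.928 with an estimated correlation). Apoptosis genes (0.16) passed without WT E2 replicate 2 (camera, adjusted p = 0.0338, and 0.804 with an estimated correlation) and repair genes (−0.10) without KO-labelled untreated replicate 2 (camera, adjusted p = 0.0391, and 0.863 with an estimated correlation).

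**Figure D2:**
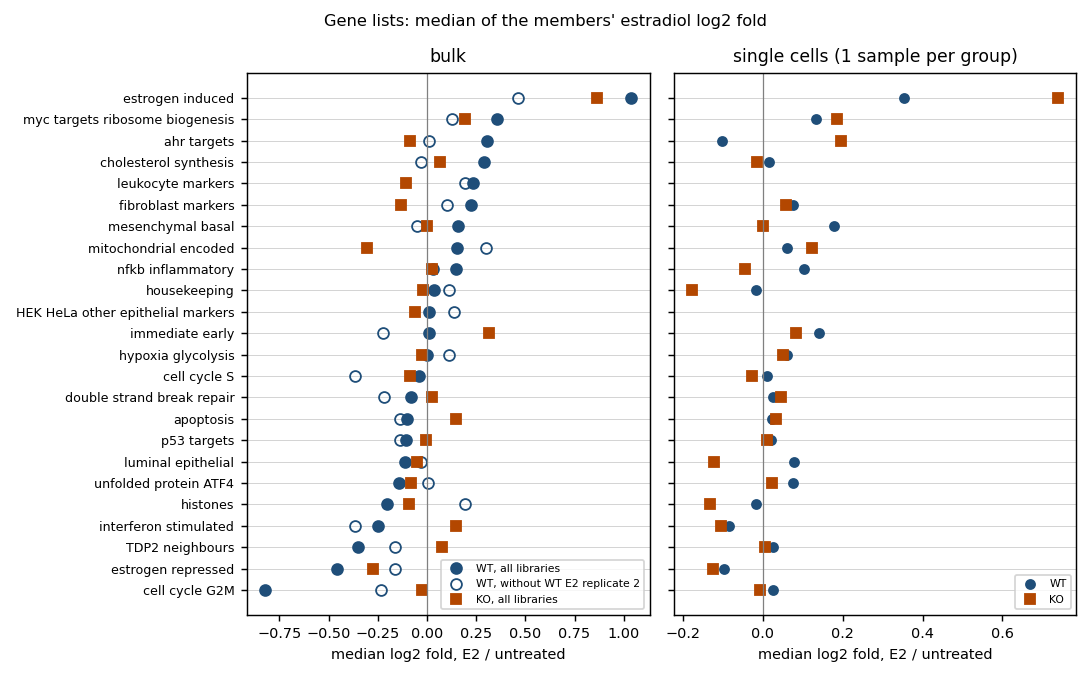
Median log2 fold of E2 against untreated (x axis) for each gene list (y axis), in bulk on the left and single cells on the right, for WT and KO-labelled samples. Open circles leave out WT E2 replicate 2, where the WT median of estrogen-induced genes is 0.46 against 1.04 with all libraries; the leukocyte and other epithelial lists have no single-cell point.

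Whether the E2 answer differed between the lines was tested as the difference of the log2 folds, and no gene passed. At an unadjusted p under 0.05 there were 355 genes, fewer than the 973 of chance, and edgeR without the block, DESeq2 and voom also called 0 genes. Without WT E2 replicate 2 the difference was −4.13 for RN7SL2 and −4.19 for TUBA1B-AS1, the latter named after its values were seen. Calls made without a WT E2 library do not measure the spread of that group. MYC had a difference of 0.63 (SE 0.40, adjusted p = 1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with −0.01 and 1.33 in the pairs. Without WT E2 replicate 2 it was 0.12, and without WT E2 replicate 1 it was 1.21. CCND1 had a difference of 0.18 (SE 0.29), which turned to −0.03 without WT untreated replicate 2 and was 0.39 without KO-labelled untreated replicate 1. The smallest unadjusted p, none of which passed with all libraries, belonged on the positive side to the interferon-induced genes IFIT1 (1.74, SE 0.41) and IFIT3 (1.48, SE 0.38), CHASERR (1.22), the mitotic kinase CDK1 (1.19, SE 0.35) and ANKRD20A18P (3.44). On the negative side they were PMS2P14 (−3.49), RN7SL2 (−3.26), RN7SL1 (−2.52), HYPK (−1.86) and TSSK3 (−3.29). RN7SL1 and RN7SL2 are near-identical copies and ANKRD20A18P and PMS2P14 are pseudogenes, so their counts are uncertain. The values nearest 0 with 1 library left out were 0.78 for CDK1 (without WT untreated replicate 2), −1.93 for PMS2P14 (without KO-labelled untreated replicate 2), and −1.81, −1.46 and −1.17 for RN7SL2, RN7SL1 and HYPK (without WT E2 replicate 1). The median SE of a difference was 0.427.

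Estrogen-induced genes as a group did not differ in their E2 fold between the lines, with a median difference of 0.004 and 28 of 55 positive (camera, adjusted p = 0.452). That median was 0.43 without WT E2 replicate 2 (camera, adjusted p = 1.19e-07, and 0.757 with an estimated correlation) and −0.38 without WT E2 replicate 1 (camera, adjusted p = 0.00037, and 0.594 with an estimated correlation). The E2 fold of G2M genes was higher in KO-labelled libraries in 53 of 55, with a median difference of 0.76 (camera, adjusted p = 6.82e-26), such as CDK1, SMC4 (1.03) and NUF2 (1.33), and without WT E2 replicate 2 the median was 0.16 (adjusted p = 0.034), with NUF2 at 0.73. It was 1.55 without WT E2 replicate 1, and SMC4 stood at 0.66 without WT untreated replicate 2. Interferon-stimulated genes had a median difference of 0.46 with 35 of 45 positive (camera, adjusted p = 5.66e-12), such as IFIT1 and IFIT3, with 0.24 without KO-labelled untreated replicate 2 and 0.75 without KO-labelled untreated replicate 1. Cholesterol synthesis (median −0.31) and mitochondrially encoded genes (−0.42) each had an adjusted p of 0.000875. Without WT E2 replicate 2 the cholesterol median was −0.006, and the mitochondrial call was lost without KO-labelled E2 replicate 1 (median −0.07). Their largest medians were −0.50 without WT E2 replicate 1 and −0.79 without KO-labelled E2 replicate 2. Immediate early genes (median 0.20, adjusted p = 0.0118), TDP2 neighbours (0.36, 0.0198), repair and estrogen-repressed genes (0.15 and 0.18, each 0.0391) were called by camera and each lost the call without at least 3 of the libraries taken singly. With 1 library left out, the immediate early median turned to −0.19 without WT untreated replicate 1 and reached 0.38 without WT untreated replicate 2. TDP2 neighbours ranged from 0.23, without WT E2 replicate 2 (adjusted p = 0.119), to 0.50, repair genes from 0.04 to 0.36 and estrogen-repressed genes from 0.06 to 0.68. With an estimated correlation every called list of this comparison had an adjusted p of 0.595. The lists not yet named had adjusted p between 0.1 and 0.898. The 0.898 is that of S phase genes, which passed without each of the 8 libraries, 4 times upward and 4 times downward, with medians from −0.316 to 0.381, the latter without WT E2 replicate 2 (camera, adjusted p = 5.82e-05, and 0.757 with an estimated correlation). Apoptosis (0.13) and housekeeping genes (−0.13) also passed without that library (camera, adjusted p = 0.0454, and 0.757 with an estimated correlation). Leaving out WT E2 replicate 1 let AHR targets pass at −0.20 (camera, adjusted p = 8.89e-08, and 0.191 with an estimated correlation). Histones (0.57), luminal genes (0.18), ATF4 genes (0.34) and MYC target and ribosome biogenesis genes (−0.28) passed there too (camera, adjusted p of at most 0.00843, and 0.594 with an estimated correlation). NF-κB genes passed at −0.53 without WT untreated replicate 1 (camera, adjusted p = 0.000737, and 0.598 with an estimated correlation).

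Without treatment, no gene passed between KO-labelled and WT libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the lowest adjusted p was 0.0688. At an unadjusted p under 0.05 there were 954 genes, voom and edgeR without the block called 0, and DESeq2 called 36, 17 higher and 19 lower. Leaving out either WT E2 library gave 27 calls and leaving out WT untreated replicate 2 gave 3. Cell cycle groups fell in KO-labelled libraries. Transcript GC explained 37.7% of the variance of the log2 deviation from the median library in KO-labelled untreated replicate 2. It explained 26.1% in WT untreated replicate 1. Both libraries enter this comparison, and GC as a cause of the falls was not tested. Of 55 G2M genes 2 were positive, with a median log2 of −0.44 (camera, adjusted p = 8.41e-12), such as CDK1 (−1.02) and TMPO (−0.64). Of 44 S phase genes 2 were positive, with a median of −0.37 (camera, adjusted p = 1.16e-08), such as the DNA repair and nucleotide genes MSH2 (−0.61), RAD51AP1 (−0.84) and RRM2 (−0.77). Repair genes fell by a median of 0.20 (camera, adjusted p = 0.000488), with BRCA2 at −1.02 and TOP2A at −0.91. With an estimated correlation these 3 lists had an adjusted p of 0.741. All 3 calls were lost without WT untreated replicate 2, where the G2M median was −0.06 (adjusted p = 0.424) and the repair median −0.08, with CDK1 at −0.58, RRM2 at −0.36 and TOP2A at −0.37. Without KO-labelled untreated replicate 2 the S phase median was −0.07, with MSH2 at −0.34, RAD51AP1 at −0.49 and BRCA2 at −0.52. The largest medians were −0.79 for G2M genes without WT untreated replicate 1, and −0.77 and −0.32 for S phase and repair genes without KO-labelled untreated replicate 1.

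All 6 measured fibroblast markers were higher in untreated KO-labelled libraries, with a median log2 of 0.48 (camera, adjusted p = 0.000296, and 0.581 with an estimated correlation), and 2, ACTA2 (1.22) and COL5A1 (1.18), passed when adjusted over the list alone. This call held without each library, and the median was 0.91 without KO-labelled untreated replicate 2. After E2 the bulk fibroblast median was −0.09 and the list was not called. In untreated single cells it was −0.14 in KO-labelled against WT cells, with 1 of 4 measured markers higher. LUM, DCN, PTPRC and CD3D had no UMI in any single-cell sample, while COL1A1 had UMIs in 30.6% to 32.4% of cells. Of 7 leukocyte markers 6 were higher, with a median of 0.56 (camera, adjusted p = 0.0224, and 0.583 with an estimated correlation). They included CD74 (0.98), which luminal cells can also express, and ITGAM (1.21), while LCP1 stood at −0.97, and the call was lost without the replicate block (adjusted p = 0.201). The leukocyte median was 0.13 without WT untreated replicate 2 and 0.97 without KO-labelled untreated replicate 2, and LCP1 stood at −0.54 without WT untreated replicate 1. Targets of p53 rose by a median of 0.14 (camera, adjusted p = 0.0213, and 0.583 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 0.83, PHLDA3 at 0.79 and GDF15 at 0.78, and lost the call without either untreated WT library. Their median was 0.24 without KO-labelled untreated replicate 1, and PHLDA3 stood at 0.40 without KO-labelled untreated replicate 2. Mitochondrially encoded genes rose by 0.29 (camera, adjusted p = 0.00386), and immediate early genes fell by 0.23 (camera, adjusted p = 0.00436). Estrogen-induced genes fell by 0.17 (camera, adjusted p = 0.0213), with SLC39A6 at −0.75 and CTSD at 0.74, and estrogen-repressed genes rose by 0.21 (camera, adjusted p = 0.0422). With an estimated correlation these 4 lists had an adjusted p of 0.741. The mitochondrial call was lost without WT untreated replicate 2, with a median of 0.19. The median was 0.11 for immediate early genes without WT untreated replicate 1 and 0.13 for estrogen-induced genes without KO-labelled untreated replicate 2, where SLC39A6 stood at −0.44. CTSD stood at 0.32 without WT untreated replicate 1. Without KO-labelled untreated replicate 1 the median was −0.61 for estrogen-induced and 0.09 for estrogen-repressed genes, and without WT untreated replicate 2 it was −0.43 for immediate early genes. The estrogen-repressed call was also lost without the replicate block (adjusted p = 0.131). The other lists had adjusted p between 0.054 and 0.945. Among them histones and AHR targets, each with 0.054, passed without 6 and 5 of the libraries taken singly, with medians from 0.32 to 0.54 and from 0.20 to 0.25. NF-κB genes passed at 0.48 without WT untreated replicate 1 (camera, adjusted p = 0.000163, and 0.497 with an estimated correlation) and interferon-stimulated genes at 0.10 without KO-labelled untreated replicate 2 (camera, adjusted p = 0.00298, and 0.606 with an estimated correlation). Cholesterol synthesis genes passed at −0.09 without WT E2 replicate 2 (camera, adjusted p = 0.0391, and 0.612 with an estimated correlation). MYC target and ribosome biogenesis genes passed at −0.23 without KO-labelled untreated replicate 1 (camera, adjusted p = 0.00763, and 0.773 with an estimated correlation). No list of this comparison passed with an estimated correlation, where the lowest value for histones was 0.658 and for AHR targets 0.458.

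After E2, no gene passed between KO-labelled and WT libraries either, with a lowest adjusted p of 0.0511 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 1290 genes, voom and edgeR without the block called 0, and DESeq2 called 145, 70 higher and 75 lower. Leaving out WT E2 replicate 2 gave 18 calls and leaving out WT E2 replicate 1 gave 1234. Interferon-stimulated genes rose, with 41 of 45 positive and a median log2 of 0.45 (camera, adjusted p = 3.38e-15, and 0.466 with an estimated correlation), and 8 passed when adjusted over the list alone. They included the antigen presentation genes HLA-A (0.99, SE 0.19), HLA-C (0.89) and HLA-B (0.95), which share sequence, and IFIT3 (1.23). Targets of p53 rose by a median of 0.25 (camera, adjusted p = 3.99e-05, and 0.366 with an estimated correlation), with CDKN1A at 0.79, TP53INP1 at 1.20 and BBC3 at 1.10. Both calls held without each library, and the p53 median was 0.11 without KO-labelled E2 replicate 2. CDKN1A stood at 0.42 without KO-labelled E2 replicate 1, and TP53INP1 at 0.61 and BBC3 at 0.63 without WT E2 replicate 2.

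The other calls after E2 were each lost or turned when a single library was left out. G2M genes rose with 48 of 55 positive and a median of 0.29 (camera, adjusted p = 3.16e-06, and 0.734 with an estimated correlation), and fell with a median of −0.27 without WT E2 replicate 2 (adjusted p = 3.46e-09). S phase genes fell with 4 of 44 positive and a median of −0.44 (camera, adjusted p = 1.46e-07, and 0.734 with an estimated correlation), and cholesterol synthesis genes with 1 of 27 positive and −0.39 (camera, adjusted p = 1.46e-07, and 0.566 with an estimated correlation). Both medians were −0.06 without WT E2 replicate 2 (adjusted p = 0.438 and 0.642). Estrogen-repressed genes rose by 0.39 (camera, adjusted p = 3.16e-06, and 0.566 with an estimated correlation), or 0.27 without that library (adjusted p = 0.14). MYC target and ribosome biogenesis genes fell by 0.16 (camera, adjusted p = 0.00151) and histones rose by 0.50 (camera, adjusted p = 0.00546), each with 0.734 with an estimated correlation, and each had a median of 0.06 without that library. With WT E2 replicate 1 left out instead, the medians were 1.04 for G2M, −0.79 for S phase, −0.69 for cholesterol synthesis, 1.05 for estrogen-repressed, −0.34 for ribosome biogenesis and 0.91 for histone genes. TDP2 neighbours rose by 0.27 (camera, adjusted p = 0.00538) and leukocyte markers by 0.61 (camera, adjusted p = 0.047), with HLA-DRA at 1.26 and CD74 at 0.97, each with 0.566 with an estimated correlation. The TDP2 neighbour median was 0.42 and CD74 stood at 0.44 without KO-labelled E2 replicate 1. The first call was lost without KO-labelled E2 replicate 2 and the second without the replicate block (adjusted p = 0.412). The other lists had adjusted p between 0.214 and 0.869. Among them estrogen-induced genes passed at 0.23 without WT E2 replicate 2 (camera, adjusted p = 0.00123, and 0.605 with an estimated correlation) and at −0.51 without WT E2 replicate 1 (camera, adjusted p = 5.59e-08, and 0.579 with an estimated correlation). AHR targets passed at 0.29 and −0.13 without the same libraries (camera, adjusted p = 0.00981 and 0.000223, and 0.605 and 0.29 with an estimated correlation). Fibroblast markers (0.45), mitochondrially encoded genes (−0.30) and ATF4 genes (−0.14) passed without WT E2 replicate 2 (camera, adjusted p = 0.0374, 0.00621 and 0.0301, and 0.605 with an estimated correlation). Mitochondrially encoded genes also passed at −0.46 without KO-labelled E2 replicate 2 (camera, adjusted p = 1.03e-06, and 0.726 with an estimated correlation) and at 0.22 without KO-labelled E2 replicate 1 (camera, adjusted p = 0.0354, and 0.712 with an estimated correlation).

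WT E2 replicate 2 stood apart from the other 7 bulk libraries. On the first axis of a multidimensional scaling plot it lay at −2.129, KO-labelled untreated replicate 2 at 1.299 and the others between −0.303 and 0.584. The SD of its log2 deviation from the median library was 0.554, with 0.565 for KO-labelled untreated replicate 2 and 0.235 to 0.348 for the others. After a GC trend was removed, genes on chromosome 7 lay a median of 0.261 above and genes on chromosome 6 a median of −0.171 from the median library. No other library had a chromosome median above 0.09 in size. Across 13392 genes, which are not independent replicates, E2 folds in WT and KO-labelled libraries correlated with r = 0.453, and the biological coefficient of variation was 24.2%.

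**Figure D3:**
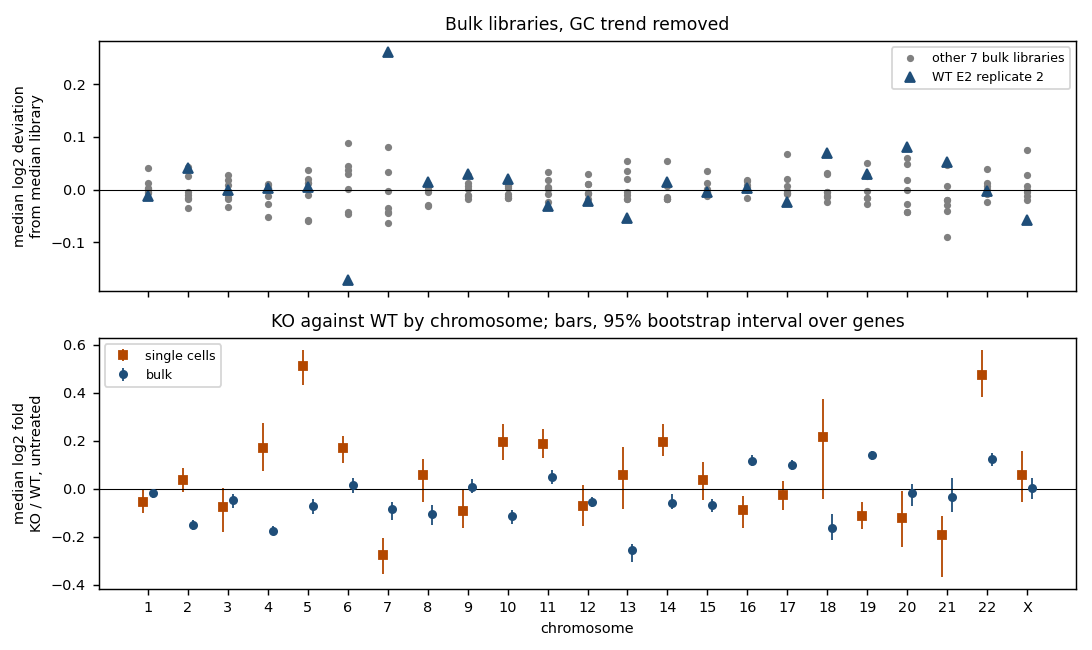
Upper panel, median log2 deviation from the median bulk library by chromosome (x axis), GC trend removed, with WT E2 replicate 2 as triangles; it reaches 0.261 on chromosome 7. Lower panel, median log2 fold of KO-labelled against WT without treatment with 95% bootstrap intervals over genes, which on chromosome 5 is 0.51 in single cells and −0.07 in bulk.

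In single cells E2 was followed by higher levels of most of its classical targets, with larger folds in KO-labelled than in WT cells. These folds come from 1 sample per condition, so their 95% intervals cover counting error only and there is no replicate check. MYC stood at 84.9 and 117.5 CPM in WT without and with E2, and at 73.9 and 164.5 CPM in KO-labelled cells. Its log2 fold was 0.47 (interval 0.37 to 0.57) in WT and 1.15 (1.07 to 1.24) in KO-labelled cells, a difference of 0.69 (0.55 to 0.82). CCND1 went from 376.7 to 525.0 CPM and from 297.5 to 466.2 CPM, log2 folds of 0.48 and 0.65. GREB1 was 1.33-fold higher after E2 in WT and 2.00-fold in KO-labelled cells, PGR 1.37-fold and 3.04-fold, EGR3 2.11-fold and 3.59-fold, and TSKU 1.25-fold and 3.87-fold. Thinning every cell to 7500 UMIs changed the GREB1 log2 fold in WT from 0.41 to 0.09, that of MYC to 0.59 and the KO-labelled PGR log2 fold from 1.61 to 1.86. TFF1 had a log2 fold of −0.02 (interval −0.05 to 0.01) in WT and of 0.32 in KO-labelled cells, where its untreated level of 4267 CPM was 4.01-fold that of WT. The variance of TFF1 UMIs between WT cells was 100.58 and 81.05 times their mean without and with E2, so counting error understates its uncertainty. The share of thinned cells with a MYC UMI was 43.8% and 56.6% in WT and 38.5% and 64.8% in KO-labelled cells. No cell type lacking MYC was present to give a background share.

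Estrogen-induced genes had a median log2 E2 fold of 0.35 in WT cells, with 49 of 55 higher, and of 0.74 in KO-labelled cells, with 52 of 55 higher, both above all 10000 random lists matched on expression. The median difference was 0.32 with 45 of 55 positive, and without treatment the same genes stood at a median of −0.39 in KO-labelled against WT cells, where random lists lay between −0.171 and 0.28. MYC target and ribosome biogenesis genes had medians of 0.13 and 0.19, and immediate early genes 0.14 and 0.08. Interferon-stimulated genes had −0.08 and −0.11 and estrogen-repressed genes −0.10 and −0.13, all outside their random lists. G2M genes had 0.03 and −0.01, within theirs. Luminal genes had a median of 0.08 in WT and of −0.12 in KO-labelled cells, where GATA3 stood at −1.04 and FOXA1 at −0.86. Mitochondrially encoded genes had medians of 0.06 and 0.12, and housekeeping genes −0.02 and −0.18. Housekeeping genes, meant as unchanged controls, thus lay below their random lists in KO-labelled cells (−0.087 to 0.056). A median of that size outside its random lists does not by itself show an E2 response. Among the largest folds in WT were SLC47A1 (4.26-fold), LHX4 (3.72-fold) and DLX3 (3.58-fold) upward and TNFRSF11B (0.146-fold), KCNJ8 (0.281-fold) and RNF43 (0.328-fold) downward. In KO-labelled cells they were SMIM32 (18.6-fold), RFPL1S (18.4-fold), KCNC1 (11.1-fold) and PTGES (10.5-fold) upward, and the helix-loop-helix regulators ID2 (0.287-fold), ID3 (0.363-fold) and ID1 (0.377-fold) and RNF43 (0.337-fold) downward. After thinning, the log2 fold went from 2.09 to 1.52 for SLC47A1 and from 3.47 to 1.01 for KCNC1, and up to 2.77 for LHX4 and 2.87 for DLX3.

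**Figure D4:**
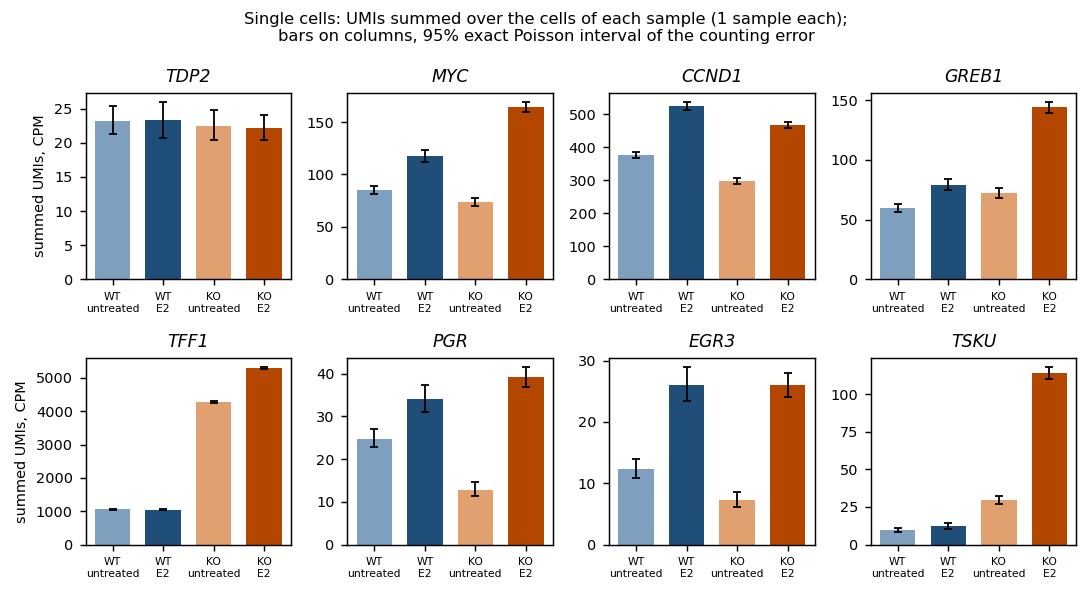
Summed single-cell UMIs as CPM (y axis, from 0) for 8 genes in the 4 samples, with bars for 95% exact Poisson intervals of the counting error. TDP2 stands between 22.2 and 23.3 CPM in every sample, while TSKU reaches 114.2 CPM in KO-labelled cells with E2 and 12.1 CPM in WT cells with E2.

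KO-labelled and WT single-cell samples differed by large folds at many genes. Without treatment LINC01419 was 43.1-fold, PSAT1, a serine synthesis enzyme with 4 UMIs in WT, 41.1-fold, and the homeobox gene HOXC8 33.1-fold higher in KO-labelled cells. LINC01291 stood at 0.0179-fold, SYT10 at 0.0233-fold, the stem cell factor SOX2 at 0.0246-fold and SLC16A7 at 0.0256-fold. After E2, INHBA stood at 0.0274-fold, KLK11 at 0.0293-fold and CT83 at 0.0318-fold of WT. Interferon-stimulated genes had a median log2 difference of 0.70 untreated and 0.62 after E2, with IFI27 at 4.38, BST2 at 4.18 and IFI6 at 1.99 untreated but HLA-A at −1.20. Genes of the unfolded protein and ATF4 list had medians of 0.72 and 0.58, with the amino acid enzymes PHGDH at 2.72 and ASNS at 2.59 and NUPR1 at 3.61. Mesenchymal and basal genes had medians of −1.37 and −1.59, with CAV1 at −3.86, CD44 at −3.63 and ITGB4 at −2.09 but VIM at 2.53. These medians lay outside their random lists. Luminal genes had a median of −0.08 untreated, within its random lists, with AGR2 at −4.39 and AGR3 at −4.54, and of −0.32 after E2, outside them. G2M genes lay within theirs, at 0.13 and 0.09.

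Bulk and single-cell folds were set side by side across genes, which are not independent replicates. The E2 folds correlated with r = 0.303 (95% bootstrap interval 0.278 to 0.328) in WT over 11863 genes and r = 0.455 (0.421 to 0.484) in KO-labelled samples over 12342 genes. Without WT E2 replicate 2 the WT value was 0.153. The KO-labelled against WT folds correlated with r = 0.034 untreated and 0.158 after E2, and the latter was 0.040 without that library. Their SD across genes was 0.84 and 0.858 in single cells and 0.34 and 0.384 in bulk. Over 355 genes that differed strongly between the untreated single-cell samples, all 8 bulk libraries, WT and KO-labelled, correlated with the KO-labelled single-cell sample at r between 0.67 and 0.77 and with the WT single-cell sample at r between 0.2 and 0.26. The 100 genes with the largest E2 rise in KO-labelled single cells, picked on those cells, had median log2 E2 folds of 0.433 in WT and 1.23 in KO-labelled single cells. In bulk their medians were 1.23 in WT and 1.05 in KO-labelled libraries. The 100 genes with the largest rise in WT single cells went the other way, with medians of 0.827 in WT and 0.469 in KO-labelled single cells, and of 0.596 and 0.319 in bulk.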

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

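The test of GC content and the test of TDP2 loss as a cause of the smaller E2 folds in WT single cells were written before their results were seen, and every other test of an explanation in this part was chosen after its result was seen. Genes below had E2 log2 folds of opposite sign in WT and KO-labelled libraries in both replicates, and the tested difference of the folds did not pass adjustment for any of them with all libraries. Without WT E2 replicate 2 the difference for RN7SL2 was −4.13. IFIT1 had a difference of 1.74 between the mean folds, with −0.7 and −1.77 in WT and 0.04 and 0.98 in KO-labelled pairs. The difference was 1.23 for CHASERR, 1.18 for CDK1, 2.48 for ANKRD20A18P, 0.78 for TDP2 itself, 0.48 for its neighbour C6orf62 and 0.36 for its neighbour MRS2. It was −3.05 for PMS2P14, −3.12 for RN7SL2, −2.34 for RN7SL1, −1.81 for HYPK and −2.68 for TSSK3. Most of these genes entered because the naming rule picks the smallest p of that same difference.

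Signal also stood in data that no comparison used. Sample tag 3, which marks no condition, held 1626 UMIs, of which 1402 lay in KO-labelled cells with E2, while the other unused tags held between 9 and 70. The 19 barcodes with no condition had a median of 56305 UMIs, and 17 of them held at least 50 UMIs of 2 or more of tags 5 to 8, against 24 of the 2143 cells with a condition.

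WT E2 replicate 2 stood apart from the other 7 bulk libraries. GC content bias was argued against, since transcript GC explained 1.8% of the variance of its deviation. GC explained 37.7% in KO-labelled untreated replicate 2, whose deviation was about as large (SD 0.565). That library enters the E2 effect in KO-labelled libraries and the untreated comparison of the lines. WT untreated replicate 1, where GC explained 26.1%, enters that untreated comparison and the E2 effect in WT. Cells of a subline with other chromosome copy numbers could account for part of the deviation of WT E2 replicate 2. Its chromosome 7 median was 0.261 and no other library passed 0.09 in size. A stronger E2 response of the genes that answer E2 in KO-labelled libraries was argued against as the whole cause. Among genes that hardly answered there, the deviation of WT E2 replicate 2 had an SD of 0.457, and that of the other WT libraries 0.247 to 0.272. Picking genes on KO-labelled folds narrows the KO-labelled libraries (at most 0.312), so they are no fair comparison. A longer response, or a response of other genes, could not be judged this way. The copy number test was not made on DNA, so a subline stays a hypothesis.

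Single-cell KO-labelled and WT samples differed at many genes that did not differ in bulk. Separate captures were argued against, since WT cells held a median of at least 7 UMIs of tags that mark KO-labelled cells. WT single cells of another subline than the bulk WT cells fit, since each bulk WT library correlated more with the KO-labelled single-cell sample, by at least 0.41 in r. If the bulk labels hold, TDP2 loss as the whole cause was argued against. The slope of bulk on single-cell folds over those genes was 0.022 (95% interval −0.009 to 0.052). TDP2 levels did not check those labels, and bulk lines of equal TDP2 status would also give a slope near 0.

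Estrogen-induced genes had smaller E2 folds in WT than in KO-labelled single cells. TDP2 loss cannot be told apart from other causes: over the 100 genes with the largest rise in KO-labelled single cells the bulk difference had a median of −0.096 (−0.218 to 0.064), and of 0.34 (0.265 to 0.431) without WT E2 replicate 2, against 0.802 in single cells, a value that picking on those cells raises. The 100 genes with the largest rise in WT single cells went the other way, with medians of 0.827 in WT and 0.469 in KO-labelled cells, and of 0.596 and 0.319 in bulk. A higher untreated level of estrogen-induced genes in the WT sample met its prediction. The median was −0.39 for KO-labelled against WT cells, where random lists lay between −0.171 and 0.28. The same untreated values enter the E2 folds, so a higher untreated WT level lowers the WT folds by arithmetic. The prediction therefore could not test this cause. TSKU, TFF1 and GREB1 ran against a higher untreated WT level as the whole cause. Their untreated levels were higher in KO-labelled cells, by 1.60, 2.00 and 0.27, and so were their E2 folds, by 1.64, 0.34 and 0.59. Untreated levels in 1 sample per line cannot separate the line from its culture.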

How the results depend on the processing

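Voom with sample weights, the robust edgeR fit and lists with a library left out were chosen after seeing the data. So were bulk folds without WT E2 replicate 2, the averaged contrasts with all their settings, and the additive model. The other alternatives were fixed before. Outside left-out libraries, named genes kept direction and side of the threshold in 2571 settings, gained the threshold in 136, lost it in 61, reversed in 4 and moved in 2. With a library left out the numbers were 1836 same, 172 gained, 294 lost and 18 reversed. The 44 list calls kept their call in 37 of the settings that changed no library and lost it in 95, and with a library left out kept it in 265, lost it in 75 and reversed in 12. Only 10 of the 44 calls held without each library. They were estrogen-induced genes (E2 in both lines), G2M and interferon-stimulated genes (E2 in WT and the difference), MYC target and ribosome biogenesis genes (E2 in WT), fibroblast markers (untreated), and interferon-stimulated genes and p53 targets (after E2). Median, mean and test shared a sign in all 44 calls and not in 18 of the 76 uncalled tests. With 2 libraries per group a gene needed a fold well above the median SE to pass, and a library left alone in its group is assumed to vary like the others. Causes of the changes below were not tested.

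Without the replicate block, counts of genes were 0 for E2 in WT, 0 for E2 in KO-labelled libraries, 4 for E2 over both lines and 10 for KO-labelled against WT over both treatments, and C6orf62 reversed to 0.043 untreated. Of the list calls 37 held without the block and 7 were lost, each given beside its list, while 1 uncalled list was gained and no other list call changed. DESeq2 called 153, 79, 243 and 325 genes in the same comparisons, 36 for KO-labelled against WT untreated and 145 after E2. The additive model called 73 for E2 and 49 for KO-labelled against WT. Voom called 2 for E2 in WT. A model of the 4 libraries alone called 0 for E2 in WT, 285 for E2 in KO-labelled libraries (229 higher, 56 lower), 16 untreated and 6 after E2. Sample weights gave 5, 6 and 7 for E2 in WT, E2 in KO-labelled libraries and the untreated comparison, and RIPOR2 reversed to −0.004. The robust fit gave 2 for E2 in WT, 2 untreated and 9 after E2. RLE scaling gave 5 after E2, and the 1 CPM filter gave 1 for E2 in KO-labelled libraries. Upper quartile scaling reversed C6orf62 (0.023) and CARMIL1 (0.031) untreated. For gene lists, the estimated correlation gave 0 calls and fry 1.

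Left-out libraries moved the counts between 0 and 1599 for E2 in WT, 0 and 101 for E2 in KO-labelled libraries, 0 and 233 for the difference, 0 and 27 untreated, 0 and 1234 after E2, 3 and 1406 for E2 over both lines, and 0 and 1267 for KO-labelled against WT over both treatments. Genes that reversed had these ranges of log2 values. Untreated, they were ALDH5A1 −0.071 to 0.265, C6orf62 −0.22 to 0.164, CARMIL1 −0.06 to 0.033, CMAHP −0.207 to 0.837, KIAA0319 −0.162 to 1.029, MRS2 −0.267 to 0.008 and RIPOR2 −1.039 to 1.049. After E2 they were ALDH5A1 −0.039 to 0.367, DCDC2 −0.19 to 0.068 and GMNN −0.213 to 0.152. For E2 they were CYP1A1 −0.108 to 4.551 and CYP1B1 −0.513 to 5.395 in WT and MT-ATP6 −0.895 to 0.037 in KO-labelled libraries, and CCND1 −0.033 to 0.387 for the difference. List medians that reversed, or whose test did, were for E2 in WT cholesterol synthesis −0.03 to 0.601, repair −0.217 to 0.01 and NF-κB 0.015 to 0.643, and for E2 in KO-labelled libraries interferon 0.002 to 0.353 and mitochondrial −0.674 to 0.03. For the difference they were cholesterol −0.504 to −0.006, estrogen-repressed 0.057 to 0.676 and, in its median alone, immediate early −0.187 to 0.381. Untreated, they were estrogen-induced −0.61 to 0.132 and immediate early −0.426 to 0.108. After E2 they were G2M −0.271 to 1.042, histones 0.062 to 0.907 and MYC target and ribosome biogenesis −0.341 to 0.061.

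Of the 76 uncalled list tests 35 passed camera without at least 1 library, in either direction for S phase (all 3 E2 comparisons), estrogen-induced (the difference and after E2) and, after E2, AHR, mitochondrial and ATF4 genes. By library 15 passed without WT E2 replicate 2, 19 without WT E2 replicate 1 and between 4 and 11 without another. With an estimated correlation 0 of them passed.

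In single cells, thinning moved log2 values past their intervals, and thinned values carry smaller UMI numbers. For E2 in WT they were 0.087 for GREB1, 0.593 for MYC, 1.52 for SLC47A1, 2.767 for LHX4, 2.866 for DLX3, −2.004 for TNFRSF11B and −2.062 for RNF43. For E2 in KO-labelled cells they were 1.858 for PGR, 0.331 for TFF1, 1.007 for KCNC1, −2.075 for ID2 and −1.329 for ID3. Untreated differences became −0.076 for MYC, −1.298 for PGR, 2.072 for TFF1 and 0.207 for TDP2, and those after E2 1.07 for GREB1, 2.404 for TFF1, −0.114 for CCND1 and 0.198 for TDP2. Other genes that moved are in the tables. The E2 correlation of bulk and single cells in WT was 0.356 at 200 UMIs and 0.153 without WT E2 replicate 2, and that of KO-labelled against WT after E2 was 0.04 without that library.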

Other observations

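The contrasts in this part, over both lines and over both treatments, and their tests were chosen after seeing the data. Without the replicate block both called fewer genes than given here, and far fewer for E2 (counts above). Averaged over WT and KO-labelled libraries, E2 raised 46 genes and lowered none in bulk (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), each in 4 of 4 replicate pairs. They included TSKU (log2 fold 2.33, SE 0.18, adjusted p = 0.00256), the transcription factors EGR3 (2.86, adjusted p = 0.00516), MYC (1.35, adjusted p = 0.0397), FOS (2.11, adjusted p = 0.0444) and GATA4 (3.95, adjusted p = 0.0351), and ENSG00000261578 (2.85, adjusted p = 0.00121). Channels, kinases and polarity genes KCNK5 (2.57), SGK1 (2.59) and PARD6B (1.61) rose, as did SIAH2 (1.48), the nuclear receptor cofactor NRIP1 (1.79), the retinoic acid receptor RARA (1.28), the glucose transporter SLC2A1 (1.01) and the chemokine CXCL12 (1.69). Among receptors for other signals ADRB1 (3.53), ADORA1 (2.29) and ADRA2A (2.30) rose. ADRB1 ranged from 0.158 to 5.37 CPM over the libraries and GATA4 from 0.14 to 6.35 CPM, while TSKU ranged from 58.5 to 497 CPM. The minimum mean log2 CPM of 1 was not applied to the averaged contrasts. Estrogen-induced genes had positive folds in 54 of 55, with a median of 0.91 (camera, adjusted p = 1.04e-89, and 0.203 with an estimated correlation), 11 past the threshold over all genes and 44 when adjusted over the list alone. MYC target and ribosome biogenesis genes rose with 48 of 52 positive and a median of 0.28 (camera, adjusted p = 3.76e-13, and 0.663 with an estimated correlation). All 55 G2M genes had negative folds (median −0.42, camera, adjusted p = 3.38e-17, and 0.663 with an estimated correlation). That average came from WT, with a median of −0.82, while KO-labelled libraries had −0.03 with 25 of 55 positive. Without WT E2 replicate 2 the averaged medians were −0.12 for G2M genes and 0.15 for MYC target and ribosome biogenesis genes. EGR3 lost its call without either KO-labelled E2 library, with log2 folds of 2.94 and 2.79. Leaving out a library moved the count of called genes between 3 and 1406, and MYC lost its call without any 1 of the untreated libraries or either KO-labelled E2 library.

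Averaged over both treatments, 8 genes were higher and 9 lower in KO-labelled than in WT libraries (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), each in 4 of 4 pairs. Lower genes were PCDHGB4 (−4.53, SE 0.35, adjusted p = 0.00239), GJB7 (−5.53, SE 0.43, adjusted p = 0.00239), CCDC106 (−2.82), ZNF614 (−2.47), GALM (−3.20), PHETA2 (−4.35), FLG (−5.10), the tumor antigen PRAME (−3.92) and LINC01419 (−4.02). Over the libraries FLG ranged from 0.0489 to 2.78 CPM, GJB7 from 0.0849 to 5.61 CPM and PCDHGB4 from 0.103 to 5.91 CPM. Their folds thus rest on low levels, while LINC01419 ranged from 2.79 to 226 CPM. Higher genes were CDSN (2.94), ITGB6 (2.29), the adjacent imprinted genes SGCE (3.39) and PEG10 (3.13), CBLC, CRACDL (1.35), HLA-A (0.99) and CFB (1.39). In single cells GJB7 (−4.47 untreated and −3.92 after E2), GALM (−3.45 and −3.12), ZNF614 (−1.65 and −0.89) and PEG10 (3.77 and 4.22) stood on the same side. LINC01419 (5.43 and 5.35), HLA-A (−1.20 and −1.56) and CRACDL (−1.46 and −0.74) stood on the other side. S phase genes fell with 2 of 44 positive and a median of −0.40 (camera, adjusted p = 4.93e-11), and interferon-stimulated genes rose with 35 of 45 positive and a median of 0.19 (camera, adjusted p = 1.41e-06), each with 0.614 with an estimated correlation. Their medians were −0.22 without KO-labelled untreated replicate 2 and 0.12 without KO-labelled untreated replicate 1. In the same comparison leukocyte markers rose with 6 of 7 positive and a median of 0.80 (camera, adjusted p = 0.00794), and fibroblast markers 5 of 6 positive and a median of 0.05 (camera, adjusted p = 0.00239), each with 0.434 with an estimated correlation. Other epithelial markers did not pass (median 0.14, camera, adjusted p = 0.236). The leukocyte call was lost without WT untreated replicate 2 (adjusted p = 0.114) among others, and the fibroblast call without WT E2 replicate 1 (adjusted p = 0.0521). Leaving out a library moved the count of called genes between 0 and 1267.

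The splits alone could not exclude chance for either count. For E2, 11 of the 46 called genes belonged to the estrogen-induced list of 55, fixed beforehand, among 19458 genes tested. This overlap argues against chance as the whole cause of the E2 count. An additive model with the replicate block called 73 genes for E2, and among 33 splits of the 8 libraries into 4 and 4 the highest other gave 2024, so that 2 splits, the real one included, called as many. For KO-labelled against WT it called 49, the highest other split gave 1011, and again 2 splits called as many. In both comparisons every split other than the real one and that highest one called no gene. For E2 that split grouped both untreated WT libraries with WT E2 replicate 1 and KO-labelled untreated replicate 2. For KO-labelled against WT it grouped both untreated WT libraries with WT E2 replicate 2 and KO-labelled untreated replicate 1. Given the other factor in the model, each set WT E2 replicate 2 and KO-labelled untreated replicate 2 apart. Those libraries lay at the ends of the first scaling axis (−2.129 and 1.299). The large counts thus point to these 2 libraries, and why they stood apart was not tested here.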
